A study of Mus musculus with 212 samples.

How the data were processed

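Small RNA was sequenced from the right hemisphere of whole brain of untreated mice of the LXS recombinant inbred panel, per the labels. The panel descends from the ILS and ISS strains, which were selected for long and short ethanol-induced sleep. The labels describe 212 libraries, of which 211 could be given a strain. The other library carries the name of LXS90 in one field and of LXS9 in another, and it was left in no group. The labelled libraries came from 61 strains, 59 of them LXS strains, and from 181 animals counted by strain and replicate letter. The design text of the series gives 59 strains and 175 mice. Libraries were sequenced in 5 batches, and 18 animals had more than 1 library. Library names carry the words HIGH, MED or LOW for some strains, and what was high or low is not given in the sources used here.

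The deposited miRNA values come in tables with 1 column per LXS strain and no column for ILS or ISS. Values of the first table are a normalized signal that the authors scaled by a method not given in the sources used here. The sums per strain ran from 12164326 to 15093719. The second table holds variance-stabilized values that the authors made on a log2-like scale, with a floor of 3.87 that 422 of 51979 values share. Its slope against log2 of the normalized signal was 0.79 for miRNAs with a mean normalized signal from 100 up to 100000 and 1.02 above that, so differences of most miRNAs are compressed in it. Each strain value was used as the authors' value, and no error per strain can be given. The number of reads behind a value is unknown. Of 881 features, 86 carried no miRNA name and 40 joined several precursors or miRNAs under 1 value, per the file headers and identifiers.

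The mRNA values are log2 expression values that the authors deposited per gene, under a header that names probes; the platform, tissue and normalization are not given in the sources used here. Column medians lay between 7.11 and 7.24. Column names hold a strain, an animal number and a set number. Columns were used where the name shows a strain with at least as many labelled small RNA libraries as columns. This gave 23 columns: 6 ILS, 6 ISS, 5 LXS41 and 6 LXS80. The other 376 columns were not used. The libraries counted by this rule include repeats of single animals. ILS had 7 libraries from 3 animals and ISS 8 from 2, and LXS41 and LXS80 also had repeats. The profiles therefore cannot be matched to labelled animals. The labels do not describe these profiles, so p-values measure the spread between them as named. Spearman correlations between profiles ran from 0.983 to 0.994, and no pair was identical. Gene symbols were matched by gene identifier for 26820 of 27123 rows. Coordinates are not given because no genome build is named for these tables. The number of profiles limits the precision.

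For mRNA, genes at or above 6 on the log2 scale in at least 5 profiles were kept, which left 20617. Strain means were fitted over all 23 profiles with limma 3.58.1 in R 4.3.3, with an intensity trend and robust empirical Bayes as in all fits, and ILS minus ISS was tested as a contrast. An F test over the 4 strains used the same settings. For miRNAs, limma was run on log2(normalized value + 1) with the strain as the replicate, over 647 features with a mean normalized value of at least 10. HIGH minus LOW was tested with the share of each strain's libraries in each sequencing batch as covariates. The batch test was an F test of those shares. A fold on the log2(value + 1) scale understates the change of low features. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Gene lists were tested with camera, with a preset correlation of 0.01 and again with an estimated one. The 13 gene lists and 16 miRNA lists were fixed before the data were examined, as were the groups, the planned comparisons and the rule for named genes. The filters, the trend and robust settings and the use of the strain as the unit of the batch test were chosen after the tables were seen.

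That rule names the 10 largest rises and 10 largest falls past the test for mRNA, 2 members of each gene list with the smallest p, the 6 host genes with the smallest p, up to 10 miRNAs with the smallest p for HIGH against LOW, the 6 miRNAs with the largest batch F and the 5 most abundant miRNAs. For host genes the p is that of ILS against ISS, since the planned correlation was not made. The rule had also named miRNAs by a strain test and by an ILS against ISS test, which need values per animal. In place of the first, the 12 miRNAs with the largest SD between strains after removal of batch shares are named, a choice made after the tables were seen. Other members of lists, and a set of 16 cerebellar genes, were named after their values were seen. A gene that the rule names is not reported here.

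The tests planned for miRNA counts per animal (strain effect, intraclass correlation, ILS against ISS, repeat libraries of 1 animal, and batch within animals) were not made, because the tables used here hold 1 normalized value per strain. The batch test over strains replaces the one within animals. The planned correlation of miRNAs with their host genes was not made, because only 2 strains had both kinds of value in the columns used.

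The scripts were tested on simulated data. Noise was drawn independently for each gene or miRNA, so variation shared between them was not simulated. With the spread of the real profiles and 200 of 20617 genes changed, the ILS against ISS test recovered 56% of changes of 0.25 log2, 89% of changes of 0.5 and 99% of changes of 1. The 4-strain F test recovered 57% at 0.25 and 89.5% at 0.5. With 60 of 647 miRNAs changed in HIGH strains, the HIGH against LOW test recovered 45% of changes of 0.5 log2, 93.3% of changes of 1 and 100% of changes of 2. The batch test recovered 36.7% at 0.5 and 96.7% at 1. Alternatives included other filters, scalings, pseudocounts, the variance-stabilized table, set or tag terms, and leaving out each mRNA profile in turn.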

Results

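The series profiled small RNA in the brains of an LXS recombinant inbred panel that is used to study responses to alcohol. The miRNA tables held 1 value for each of 59 LXS strains. In the labels, 9 strains carried the tag HIGH, 10 MED, 10 LOW and 32 no tag; 8, 9, 10 and 32 of them were in the miRNA tables. Sequencing batches 1 to 5 held 18, 42, 48, 41 and 62 of the grouped libraries. The mRNA table gave 6 profiles of ILS, 6 of ISS, 5 of LXS41 and 6 of LXS80. ILS and ISS are the parents of the panel, the long-sleep and short-sleep lines. Of each parent, 3 profiles were in set 1, and the others were in set 11 for ILS and in set 15 for ISS.

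The comparison of ILS with ISS asks which transcripts differ between the parents. Nr4a1, an activity-induced nuclear receptor, was 2.31-fold higher in ILS, at 10.25 ± 0.26 (log2, SD, n = 6) against 9.04 ± 0.45 in ISS (n = 6; adjusted p = 0.000108). Lama4, a laminin chain of vascular basement membranes, was 2.15-fold higher, at 8.48 ± 0.13 against 7.38 ± 0.14 (adjusted p = 4.79e-11). In the other direction, Etnppl, the phosphoethanolamine phospho-lyase of astrocytes, was 3.07-fold lower in ILS, at 6.55 ± 0.17 against 8.17 ± 0.20 (adjusted p = 3.18e-10). Ceacam1, a cell adhesion molecule, was 3.20-fold lower, at 6.49 ± 0.44 against 8.17 ± 0.50 (adjusted p = 4.54e-05). H2-D1, a class I histocompatibility gene, was at 6.40 ± 0.41 in ISS and at 4.39 ± 0.20 in ILS (adjusted p = 3.61e-05); the ILS level lies under the filter of 6, so no fold is given.

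In all, 698 genes were higher and 869 lower in ILS among 20617 tested (limma). A strain variant under the probes of a gene could give such a difference without a change in its transcript. This was not tested for single genes here. The differences were mostly small: the median absolute log2 difference of the called genes was 0.25, and 24 genes differed by at least 2-fold, 11 upward and 13 downward. The largest rise was in the transcript A830036E02Rik (ENSMUSG00000084890), by 2.34 on the log2 scale (SE 0.13). Gm8840 rose by 1.75, 1700016P03Rik by 1.51, 1810020O05Rik by 1.17, Gm13853 by 1.11, Mir7220 by 1.10, 4833420G17Rik by 1.03 and 2610044O15Rik8 by 1.01. The other large falls were in the kallikrein gene Klk1b22, which fell by 1.53, and in Gm5148, which fell by 1.43, Gm11826 by 1.36, Gm11539 by 1.26, Vmn1r-ps74 by 1.20, Gm6969 by 1.19 and Gm22751 by 1.15. Of these 20 genes, 14 had symbols of predicted genes, RIKEN transcripts, pseudogenes or miRNA genes, against 21.6% of the genes tested. Probes of such genes can share sequence with related genes, so their identity is uncertain. H2-D1, Klk1b22, Mir7220, 1810020O05Rik, Vmn1r-ps74 and Gm22751, 6 of the 20, had a mean under 6 in at least 1 parent and are not shown to lie above background there, so the size of their differences is uncertain. With set as a term Klk1b22 did not pass (adjusted p = 0.175), though within set 1 it did, with the same difference of -1.21 (adjusted p = 0.0374). In the later sets 1700016P03Rik differed by 0.60 and did not pass (adjusted p = 0.292), against 2.42 in set 1. Gm13853, Mir7220 and Vmn1r-ps74 did not pass within set 1 (adjusted p = 0.368, 0.406 and 0.0553) or the later sets (adjusted p = 0.0616, 0.0785 and 0.161). Gm22751 did not pass in the later sets (adjusted p = 0.629), and it did not without ILS replicate 2, ISS replicate 2 or ISS replicate 3 (adjusted p = 0.0562 to 0.0618).

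ILS and ISS shared only set 1. Within it, with 3 profiles of each parent, 163 genes were higher and 131 lower in ILS, and 254 of these 294 were among the calls from all profiles. With set as a term in the model, 496 genes passed. As only set 1 held both parents, the differences of that model are those of set 1, and only the estimate of the spread differs. Of the 1567 called genes, 1566 had the same sign in set 1 and all 1567 in the later sets, although these profiles were themselves used to call them. No gene passed limma's test that the difference itself differed between set 1 and the later sets, and 914 had an unadjusted p under 0.05. With 3 profiles of each parent on either side, this test can miss such changes, so it does not show that the sets agree.

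The profile ILS replicate 4 stood apart in genes with strong expression in the cerebellum. A set of 16, chosen after values of this profile were seen, was examined, and all 16 were lower in it than in each of the 22 other profiles of ILS, ISS, LXS41 and LXS80. Gabra6, a GABA-A receptor subunit gene of granule cells, was at 6.51 in it and at 10.01 to 10.61 in the others. Cbln3 was at 7.21 against 9.98 to 10.81, Fat2 at 6.89 against 9.32 to 10.13, and En2 at 6.59 against 8.11 to 9.26. Without this profile 543 genes were higher and 697 lower in ILS, 1240 in all. The calls of Aqp4, Mobp, Aldh1a1, Acadvl, Pdyn and the microglia list were then lost. Aqp4 and Mobp still differed by -0.20 each, Aldh1a1 by -0.24, Acadvl by -0.15 and Pdyn by 0.17, and the mean of the list was 0.12. All but Mobp also lost their calls without other single profiles, so they do not rest on this profile alone. For Aqp4, Acadvl and Pdyn, though, the highest adjusted p of such losses by limma came without this profile (0.0674, 0.0757 and 0.112). The same held for the microglia list by camera (adjusted p = 0.134). For Aldh1a1 the highest came without ISS replicate 6 (adjusted p = 0.111 by limma). With the ILS and ISS profiles alone in the model, Aqp4, Aldh1a1, Acadvl and Pdyn did not pass (adjusted p = 0.0532, 0.105, 0.0745 and 0.0662).

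Activity-induced transcription factors and signalling genes were higher in ILS. Of 8 immediate early genes measured, 6 rose and none fell; adjusted over the list alone, 8 rose. Besides Nr4a1, Arc, a regulator of synaptic receptor traffic, rose by 0.90 (SE 0.18), Dusp1 by 0.69, Egr1 by 0.58, Fosb by 0.47 and Fos by 0.41. Npas4 was 0.56 higher and Junb 0.28 higher, with adjusted p = 0.0564 and 0.208 over all genes. Npas4 passed without ILS replicate 5, ISS replicate 4 or LXS41 replicate 3 (adjusted p = 0.0124 to 0.0479), with set as a term (adjusted p = 0.0150), with the stricter filter, and after quantile normalization or median centring. The list passed camera with the preset correlation (adjusted p = 2.18e-09) and did not with an estimated correlation (adjusted p = 0.115). Fos lost its call without ILS replicate 1, ILS replicate 2, ISS replicate 1, ISS replicate 2 or ISS replicate 4 (adjusted p = 0.0517 to 0.0815). The median difference over the list was 0.89 within set 1 and 0.24 between the later sets. Nr4a1 differed by 1.66 within set 1 and by 0.76 between the later sets, where it passed (adjusted p = 0.0423). Arc, Egr1, Dusp1, Fosb and Fos did not pass there, with differences of 0.39, 0.36, 0.27, 0.20 and 0.13, and Npas4 and Junb differed by 0.13 and 0.14. For the change between sets limma gave adjusted p = 0.870 for Nr4a1. LXS80 lay with ILS, at 10.48 ± 0.16 for Nr4a1 (n = 6), and LXS41 lay near ISS, at 9.25 ± 0.45 (n = 5). LXS80 shared no set with the other strains, so its level cannot be told from a difference between sets.

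**Figure D1:**
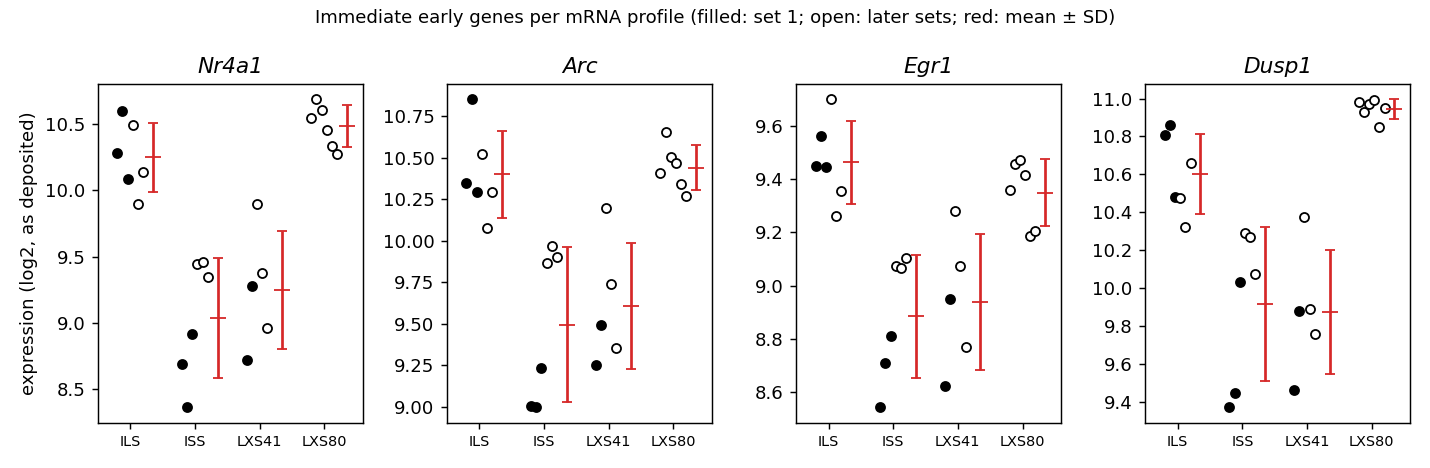
Expression (log2, as deposited) of 4 immediate early genes in each mRNA profile of ILS, ISS, LXS41 and LXS80; filled points are set 1, open points later sets, and red bars the mean ± SD. For Nr4a1 the ILS mean is 10.25 and the ISS mean 9.04, and the set 1 profiles of ISS are lower than its later ones.

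Genes of the choroid plexus, the tissue that makes cerebrospinal fluid, were lower in ILS. The tissue of these profiles is not given, and whether this comes from strain or from the tissue sampled was not tested. Of 6 measured, 4 fell and none rose; adjusted over the list alone, 5 fell. The anti-ageing hormone gene Kl fell by 0.61 (SE 0.10), the potassium channel gene Kcnj13 fell by 0.57 (SE 0.12), the folate receptor gene Folr1 fell by 0.29 and Clic6 fell by 0.26. Ttr, the abundant carrier of thyroid hormone, was at 12.92 ± 0.26 in ILS and 13.19 ± 0.06 in ISS (n = 6 each; adjusted p = 0.0788, but 0.00965 without ILS replicate 6 and 0.0148 after quantile normalization), and Aqp1 was at 6.81 ± 0.09 and 6.92 ± 0.13. The list passed camera with the preset correlation (adjusted p = 7.96e-06) and did not with an estimated correlation (adjusted p = 0.0964). Within set 1, Kl differed by -0.66 and Kcnj13 by -0.63, both still past the threshold, whereas Folr1 and Clic6 were not (adjusted p = 0.188 and 0.247). In the later sets Kl, Kcnj13, Folr1 and Clic6 did not pass (adjusted p = 0.0734, 0.302, 0.0877 and 0.0945), and Clic6 lost its call without any of ILS replicates 1 to 3 or ISS replicates 3 to 6 (adjusted p = 0.0509 to 0.0763).

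Among microglia genes, 3 of 8 measured rose and none fell; adjusted over the list alone, 3 rose and 1, Cx3cr1, fell. The complement gene C1qc rose by 0.57 (SE 0.06), C1qb by 0.53 and the calcium-binding protein gene Aif1 by 0.41. The third complement subunit gene, C1qa, was at 8.52 ± 0.10 in ILS and 8.66 ± 0.19 in ISS, and the microglial marker Tmem119 at 7.90 ± 0.08 and 7.93 ± 0.17 (n = 6 each). The list passed camera with the preset correlation (adjusted p = 0.0395) and did not with an estimated correlation (adjusted p = 0.494). Within set 1 the list did not pass (adjusted p = 0.329), and neither did C1qb and Aif1 (adjusted p = 0.07999 and 0.107). In the later sets the list and C1qc did not pass (adjusted p = 0.0527 and 0.0732). The list did not pass with the stricter expression filter (adjusted p = 0.0656), with the ILS and ISS profiles alone (adjusted p = 0.108), with set as a term (adjusted p = 0.280) or after quantile normalization (adjusted p = 0.0602), and it did not pass without ILS replicate 4, ISS replicate 1, ISS replicate 2 or LXS80 replicate 6 (adjusted p = 0.0513 to 0.134).

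Markers of other cell types were also measured. Of 9 neuron genes, 1 rose, the vesicular glutamate transporter gene Slc17a7, by 0.20 (SE 0.04), and none fell; adjusted over the list alone, 2 rose, the other being Syt1, which also passed over all genes without ILS replicates 1 or 3, ISS replicates 2 or 3 or LXS41 replicate 4 (adjusted p = 0.0329 to 0.0470). Of 7 astrocyte genes, 1 fell, the water channel gene Aqp4, by 0.26 (SE 0.07), and adjusted over the list alone the count was also 1. Gfap was at 8.70 ± 0.12 in ILS and 8.84 in ISS, and passed without ILS replicate 1 (adjusted p = 0.0495). Of 7 oligodendrocyte genes, 1 fell, the myelin gene Mobp, by 0.24, and adjusted over the list alone the count was also 1. None of 6 endothelial genes passed; adjusted over the list alone, 1 fell, Cldn5, with a difference of -0.26 (Tek -0.11); over all genes Cldn5 passed without ILS replicates 1 or 4, ISS replicate 1, or LXS41 replicates 2 or 4 (adjusted p = 0.0206 to 0.0422). None of 3 erythroid genes passed in either way; Alas2 differed by -0.14 and Hbb-bt by -0.27. Slc17a7, Aqp4 and Mobp did not pass within set 1, where they differed by 0.16, -0.22 and -0.11, or within the later sets. In the later sets alone the oligodendrocyte list passed camera with the preset correlation (adjusted p = 0.0316), and an estimated one was not tried there. With all profiles the list did not pass camera with the preset or an estimated correlation (adjusted p = 0.398 and 0.717). Aqp4 lost its call without ILS replicate 4, ISS replicate 2 or ISS replicate 3 and Mobp without ILS replicate 4 (adjusted p = 0.0561 for Mobp and 0.0569 to 0.0674 for Aqp4). For the neuron list the median and mean were below 0 and the direction of camera was up.

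Few genes of ethanol metabolism and of ethanol-sensitive signalling passed the test. Catalase, Cat, which oxidizes ethanol in brain, fell by 0.20 (SE 0.04), and the retinaldehyde dehydrogenase gene Aldh1a1 fell by 0.35 (SE 0.11); they were the 2 of 8 measured genes of this list that passed, and adjusted over the list alone 2 fell and 1, Adh5, rose; Adh5 passed over all genes after quantile normalization (adjusted p = 0.0286) and median centring. Aldh1a1 differed by -0.09 within set 1 and by -0.62 between later sets, and it lost its call when any of 16 single profiles was left out, those being ILS replicates 2 to 5, ISS replicates 1 and 3 to 6, LXS41 replicates 2 to 4 and LXS80 replicates 2 to 5 (adjusted p = 0.0502 to 0.111), and with no expression filter (adjusted p = 0.0577). Cat did not pass within set 1 (adjusted p = 0.326) or the later sets (adjusted p = 0.118). Of 13 GABA-A receptor genes and of 14 ionotropic glutamate receptor genes, none passed by limma in either way of adjustment with all profiles. Gabra2 was 0.17 higher and Gabrg3 0.13 higher, and Grin1 was 0.10 higher with Gria4 at -0.14. Gabra2 passed without ILS replicate 6 or LXS41 replicate 4 (adjusted p = 0.0319 and 0.0377) and after quantile normalization, and Grin1 without ILS replicates 1 or 3 (adjusted p = 0.0459 and 0.0130). Of 7 ethanol-sensitive potassium channel genes, 1 rose, Kcnn2, by 0.18, and adjusted over the list alone 2 rose, the other being Kcnj6, which also passed over all genes without ILS replicate 3 or LXS41 replicate 2 (adjusted p = 0.00906 and 0.0488). Kcnn2 did not pass within set 1 (adjusted p = 0.158) or the later sets (adjusted p = 0.415). The mean of the GABA-A list was below 0 and its median above it, with camera up; Gabra6, low in ILS replicate 4 alone, differed by -0.59, and without that profile the mean of the list was 0.023. The glutamate list had a median and mean below 0 with camera up.

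Of 16 opioid, dopamine, stress peptide and neurotensin genes, 1 rose and 2 fell. The neurotensin receptor gene Ntsr2 fell by 0.32 (SE 0.06), the kappa opioid receptor gene Oprk1 fell by 0.27 (SE 0.06), and Pdyn, which encodes the precursor of dynorphins, rose by 0.23 (SE 0.07). Adjusted over the list alone, 4 rose and 2 fell. Within set 1, Ntsr2 differed by -0.23, Oprk1 by -0.25 and Pdyn by 0.22, none past the threshold, and in the later sets Oprk1 and Pdyn did not pass. Pdyn lost its call without ILS replicates 2 or 4 or any ISS replicate but replicate 5 (adjusted p = 0.0515 to 0.112), and with no expression filter (adjusted p = 0.0510). Besides the immediate early, choroid plexus and microglia lists, none of the other 10 passed camera with all profiles and the filter. The potassium channel list did pass with no expression filter (adjusted p = 0.0417), in the later sets (adjusted p = 0.0343), without ILS replicate 3 (adjusted p = 0.0356) and without ISS replicate 4 (adjusted p = 0.0429), each with the preset correlation. With an estimated correlation its adjusted p was 0.396, and none of the 13 lists passed.

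Genes that host miRNAs in their introns were examined because host and miRNA can share transcription. Of 44 measured, 2 rose and 4 fell in ILS; adjusted over the list alone, 3 rose and 5 fell. R3hdm1, the host of miR-128-1, rose by 0.25 (SE 0.05), and Klhl3, the host of miR-874, by 0.22 (SE 0.06). Copz2, the host of miR-152, fell by 0.28 (SE 0.06), Htr2c, the serotonin receptor gene that hosts miR-448 and miR-1298, fell by 0.21, Acadvl, the host of miR-324, fell by 0.17, and Eml2, the host of miR-330, fell by 0.16. None of these 6 passed within set 1 or within the later sets, where all kept their sign, and with set as a term Copz2 alone passed. Acadvl lost its call without any of ILS replicates 2 to 4 or ISS replicates 3 to 5, Eml2 without ILS replicates 5 or 6 or ISS replicate 4, and Htr2c without ILS replicates 5 or 6 or ISS replicates 3 or 4, with adjusted p of at most 0.0757, 0.0540 and 0.0600.

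The F test asked which transcripts differ among ILS, ISS, LXS41 and LXS80. It called 4668 genes, 22.6% of those tested, and 1475 of them were also called between the parents. Without LXS41 replicate 1 the count was 3103. Lama4 stood at 7.27 ± 0.06 in LXS41 (n = 5) and 7.45 ± 0.08 in LXS80 (n = 6), near the 7.38 of ISS. Gm6969 stood at 9.68 ± 0.08 in LXS41, near the 9.70 of ISS, and at 8.45 ± 0.17 in LXS80, near the 8.51 of ILS. Ceacam1 went the other way, with 6.57 ± 0.55 in LXS41 and 8.28 ± 0.28 in LXS80. Etnppl was between the parents in both, at 7.76 ± 0.20 and 7.65 ± 0.21. Of 180 called genes with a parental difference of at least 0.5 log2, the LXS41 mean was within 25% of that difference of ILS for 54, of ISS for 53, between these ranges for 50 and beyond both for 23. For LXS80 the numbers were 68, 54, 41 and 17. No set held all 4 strains. LXS80 was in sets 3 and 14, which held no other strain in the columns used. Its differences from the other strains therefore cannot be told from differences between sets. LXS41 had 2 profiles in set 1 and the others in sets 6 and 9, so its differences are in part confounded with set.

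In the miRNA tables, miR-181a-5p was the most abundant, with a mean of 19.6% of the normalized signal over 59 strains. It was followed by miR-26a-5p (8.72%), miR-127-3p of the imprinted Dlk1-Dio3 cluster (6.43%), miR-22-3p (5.41%) and let-7c-5p (3.98%), and these 5 made up 44.2%. By list, the Dlk1-Dio3 cluster held 15.8% of the signal, the let-7 family 8.49% and neuron-enriched miRNAs 7.01%. Unannotated features held 0.0169%. The highest strain value of miR-22-3p was 1.67-fold the lowest, that of miR-181a-5p 1.99-fold, that of miR-26a-5p 2.01-fold, that of miR-127-3p 2.18-fold and that of let-7c-5p 3.54-fold. The median feature had a 3.67-fold range.

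The widest spread between strains was in the miR-200 family, which is expressed in epithelia and in the olfactory system. miR-200a-3p ran from 357 normalized units in LXS102 to 56966 in LXS115, a 159-fold range on the log2(value + 1) scale, and miR-200c-3p had a 345-fold, miR-141-3p a 236-fold and miR-429-3p a 165-fold range. miR-200b-3p, miR-200b-5p, miR-200a-5p and miR-141-5p had ranges of 136-fold, 162-fold, 94.7-fold and 149-fold. The sensory-organ miRNAs miR-182-5p, miR-183-5p and miR-183-3p followed, with ranges of 63.3-fold, 112-fold and 62.6-fold; miR-182-5p reached 1071220 units in LXS107. An unannotated feature with a 22.8-fold range completed the 12 widest. The SD without batch was 2.04 log2 for miR-200a-3p, against 0.32 for the median feature. These are spreads of the authors' strain values, and the spread between animals of a strain cannot be separated from them. Whether they come from strain or from the tissue sampled was not tested.

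**Figure D2:**
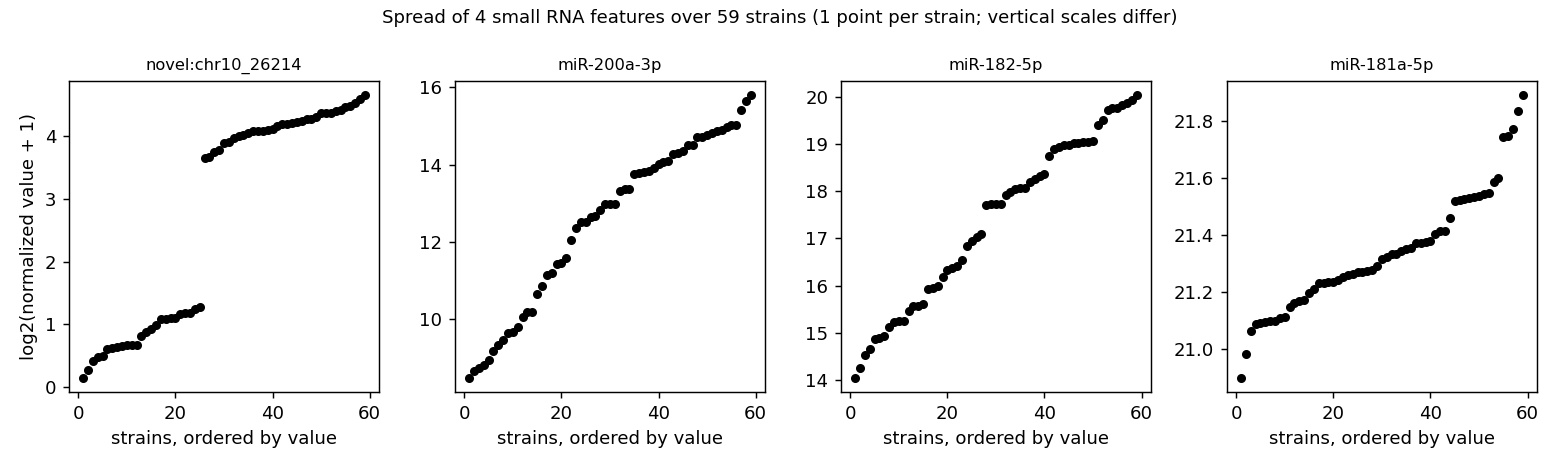
Log2(normalized value + 1) of 4 small RNA features in each of 59 strains, ordered by value within each panel; each point is the authors' value of 1 strain and vertical scales differ. miR-200a-3p spans a 159-fold range and miR-181a-5p a 1.99-fold range, and the unannotated feature at the left shows a gap between 25 lower and 34 higher strains.

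Strain values followed the sequencing batches. miR-9-5p, a neural miRNA, had a mean of 17.67 ± 0.25 (log2, SD, n = 3) in the strains sequenced only in batch 3 and of 19.26 ± 0.11 in those sequenced only in batch 5 (n = 8; adjusted p = 2.01e-21 for the batch test). miR-33-5p was at 4.81 ± 0.46 and 7.67 ± 0.49, miR-376b-5p at 9.45 ± 0.30 and 12.20 ± 0.33, miR-551b-3p at 7.62 ± 0.49 and 9.89 ± 0.22, miR-24-2-5p at 8.20 ± 0.57 and 10.47 ± 0.36, and miR-330-5p at 12.91 ± 0.18 and 14.22 ± 0.11. In all, 561 of 647 miRNAs passed the batch test by limma, 307 of them higher and 254 lower in batch 3 than in batch 5 by the fitted coefficients. Of the 8 strains of batch 5 alone, LXS9 shares its name with the library of contradictory names from batch 4, and whether its value includes that library is not known; without LXS9 and LXS90, 564 miRNAs passed. Batch shares held a median of 41.0% of the variance between strains. The 3 strains of batch 3 alone all carry a tag and the 8 of batch 5 alone carry none, so these means set tagged against untagged strains as well as batches. With the tags as further terms 48.8% of miRNAs passed.

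**Figure D3:**
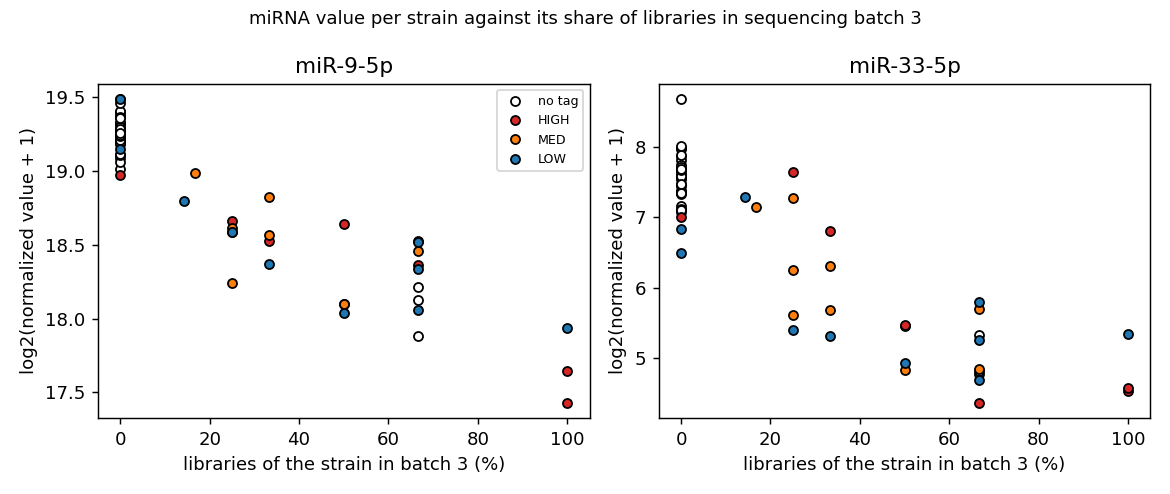
Log2(normalized value + 1) of miR-9-5p and miR-33-5p in each of 59 strains against the percentage of the strain's libraries sequenced in batch 3; colours give the tag in the library names. Strains sequenced only in batch 3 average 17.67 for miR-9-5p, and those sequenced only in batch 5 average 19.26.

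In the lists, members are counted as rising or falling by the single coefficient of batch 3 against batch 5, not by the batch test over all batches. By miRNA list, the smallest camera p for batch 3 against batch 5 was that of vascular miRNAs, of which 5 of 6 fell and none rose in batch 3, the same adjusted over the list alone. miR-145a-5p fell by 1.71 (SE 0.23), miR-126a-3p by 1.42 (SE 0.13) and miR-143-3p by 0.94. This list passed camera with the preset correlation (adjusted p = 0.0248) and did not with an estimated correlation (adjusted p = 0.441). The other 15 lists did not pass. In the let-7 family 9 of 19 rose and 4 fell, with let-7b-5p up by 1.18 and let-7g-5p down, where it fell by 0.42. In the Dlk1-Dio3 cluster 28 of 84 rose and 30 fell. Rises and falls numbered 7 and 9 of 22 neuron-enriched miRNAs, 3 and 1 of 5 oligodendrocyte miRNAs, 1 and 2 of 7 leukocyte and microglia miRNAs, and 4 and 2 of 7 erythroid miRNAs. They numbered 5 and 4 of 9 choroid plexus and ciliated cell miRNAs, 4 and 0 of 9 pituitary, pineal and sensory miRNAs, 0 and 1 of 5 hindbrain Hox cluster miRNAs, 2 and 0 of 4 striated muscle miRNAs, and 0 and 4 of 5 astroglia and reactive miRNAs. They numbered 7 and 7 of 25 Sfmbt2 cluster miRNAs, 3 and 3 of 14 miRNAs of the miR-17-92 and related clusters, and 13 and 14 of 36 miRNAs linked to alcohol in earlier literature, and 0 of 8 miR-200 family members. By the batch test over all batches, 7 of the 8 miR-200 family members passed, as did 7 of 7 leukocyte and microglia miRNAs and 75 of 84 of the Dlk1-Dio3 cluster. Adjusted over the list alone, rises and falls were 10 and 4 in the let-7 family, 6 and 6 in the Sfmbt2 cluster and 2 and 3 in the miR-17-92 clusters, with no other list changed. For the miR-17-92 clusters and the alcohol literature list the median was above 0 and camera pointed down.

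No miRNA differed past the threshold between strains tagged HIGH and LOW. By limma, 0 of 647 passed, the smallest adjusted p was 0.798, and 26 had an unadjusted p under 0.05, where 32.4 are expected by chance. The smallest p was that of miR-190a-5p, at 7.73 ± 0.68 (log2, SD, n = 8 strains) in HIGH and 8.43 ± 0.51 in LOW (n = 10), a difference of -0.56 (SE 0.18) after allowance for batch. miR-181c-5p differed by 0.27 and miR-181a-5p by 0.22. Batch shares held 81.0% of the variance of miR-190a-5p. miR-344-3p differed by 0.23, miR-16-1-3p by 0.35, miR-582-3p by 0.26 and miR-381-3p by 0.21, and miR-6996-5p by -0.37, miR-216a-5p by -0.40 and miR-338-5p by -0.25. None of the 16 miRNA lists passed camera, with the preset or an estimated correlation, and no member passed when adjusted over the list alone. The hindbrain Hox cluster had the smallest list p, with a median difference of 0.35 over 5 members (adjusted p = 0.111), and the miR-200 family had a median difference of 0.64 over 8 members (adjusted p = 0.297). In simulations, 93.3% of 1 log2 changes were recovered but 45% of 0.5 log2 changes, so differences of the smaller size would often be missed. These shares are averages over miRNAs with independent noise. They do not hold for miRNAs that vary widely, such as miR-200a-3p, where the SE of HIGH minus LOW was 0.98. The median and the direction of camera differed in sign for the oligodendrocyte, pituitary and let-7 lists.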

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

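The tests of the immediate early genes and of the scaling were chosen after the results were seen; those of tags and of other splits were written down beforehand.

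Single samples stood apart from the rest of their group in 8 of 160 groups tested, and chance gives about 1 in 20. The lowest ILS profile of Mir7220 was at 4.86 against 5.90 for the nearest, a gap of 0.637 of the range. The highest ISS profile of Alas2 was at 7.66 against 7.20, a gap of 0.632 of the range. The lowest ILS profile of Gria4 was at 10.02 against 10.34, a gap of 0.713 of the range. The lowest ISS profile of Ttr was at 13.08 against 13.20, a gap of 0.742 of the range. In ILS replicate 4, genes with strong expression in the cerebellum stood apart from the other ILS profiles: Gabra6 was at 6.51 against 10.24 (0.920 of the range), Cbln3 at 7.21 against 10.34 (0.956) and Fat2 at 6.89 against 9.32 (0.869), these 3 having been picked after their values were seen. The lowest HIGH strain of miR-181c-5p was at 17.26 against 17.75, a gap of 0.571 of the range.

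Immediate early genes were higher in ILS than in ISS. A difference between sets alone would leave little within set 1, but the median difference over the 8 genes there was 0.89 log2. Between the later sets it was 0.24, so the size of the difference is not settled. Independent strain variants under the probes would move genes both ways, but all 8 of the list lay on the ILS side (exact two-sided binomial p = 0.00781), the observation that had prompted the test. The genes varied together from profile to profile within strains, with a mean correlation of 0.783. Sets were not removed from this value. In ISS the mean over the list was 8.22 to 8.63 in set 1 and 8.84 to 8.92 in set 15. The correlation can therefore come in part from sets, and it does not single out a state of the animals at collection, such as handling. That state and a strain difference in basal activity both stay open, because no record of collection is at hand for these profiles.

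Strain values of miRNAs followed sequencing batch. If the HIGH, MED and LOW tags stood behind this, untagged strains would show little of it, but 61.2% of the miRNAs passed the batch test among them. Untagged strains had no library in batch 2, and only LXS8, LXS50 and LXS100 of them had libraries in batch 3. This share therefore says nothing of batch 2 and little of batch 3, for which the tags are not excluded. With the tags as further terms over all strains, 48.8% of the miRNAs passed. A scaling factor per strain would move all miRNAs alike, but the differences between batches 3 and 5 had an interquartile range of 1.01 log2 over the miRNAs, 6.50 times their median standard error. Median-of-ratios rescaling moved strain values by at most 0.10 log2 and tests little; a scaling that depends on abundance stays open. What differed between the batches is not recorded, and strain differences that coincide with batch stay open for single miRNAs because most strains were sequenced in few batches.

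Chance can be excluded for the count of genes between ILS and ISS: 1 of 100 splits drawn from the 462 of the 12 profiles, the real one, called as many as 1567, and the highest of the others called 19. The split of set 1 from the later sets called 0. Each side of that split held both parents, so it cannot show a difference between set 11 and set 15. Chance can be excluded for the 4-strain test, where 1 of 100 splits, the real one, called as many as 4668 and the highest other called 1. Those splits moved single profiles without regard to set, so they cannot tell strain from set. Chance can be excluded for the batch test, where 1 of 100 assignments, the real one, called as many as 561 and the highest other called 254. It cannot be excluded for HIGH against LOW: 75 of 100 splits gave at least the 26 miRNAs at an unadjusted p under 0.05, and the highest other gave 240. A split with that many points to a structure of the samples, and what gave it was not tested.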

How the results depend on the processing

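Most alternatives for mRNA and the table, pseudocount, tag and strain alternatives for miRNAs were chosen after seeing the data; no filter for either, the stricter miRNA filter, median-of-ratios rescaling, no batch terms and the estimated correlation were planned. No paired analysis was possible because miRNA columns hold 1 value per strain and mRNA columns carry no replicate letter. Planned count-based tests, libraries left out for low depth or repeats, single batches, leaving out ILS or ISS libraries, and host gene alternatives were not run, because no values per library were used. The cause of the changes below was not tested, except that single sets hold fewer profiles and the stricter miRNA filter fewer miRNAs.

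Against 698 genes higher and 869 lower in ILS, 1567 in all, set 1 alone gave 163 and 131 (294), the later sets alone 88 and 195 (283), and set as a term 260 and 236 (496). Quantile normalization gave 1127 and 1203 (2330), and median centring 837 and 864. Leaving out each profile gave 1240 to 1644 genes, 521 to 744 higher and 647 to 928 lower. The 4-strain count of 4668 ran from 3103, without LXS41 replicate 1, to 5054. The 3 gene lists past the threshold became 0 with an estimated correlation, and 2 to 4 without single profiles; the microglia list was the one lost in each such case, without ILS replicate 4, ISS replicate 1, ISS replicate 2 or LXS80 replicate 6. It was also lost with the stricter filter, the ILS and ISS profiles alone, either set alone, set as a term and quantile normalization. Set as a term gives the differences of set 1, so it and set 1 alone are not separate checks.

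For HIGH against LOW the count past the threshold stayed at 0 in every alternative run. The 26 miRNAs at an unadjusted p under 0.05 became 15 with the stricter filter and 45 on variance-stabilized values. The 561 miRNAs of the batch test became 330 with the stricter filter and 316.0 with tags as terms. All 77 values for HIGH against LOW and 53 for batch of single miRNAs under alternatives kept their direction and side.

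Of values for named genes, 75 lost and 13 gained the threshold under other settings, and 55 and 21 when 1 profile was left out. Hbb-bt, not past the threshold, turned to 0.038 in set 1 and with set as a term, and Tmem119 to 0.039 in both. Means of lists that did not pass changed sign near 0: neuron genes were at 0.014 in set 1 and with set as a term and at 0.0063 after median centring, oligodendrocyte genes at 0.00099 and GABA-A receptor genes at 0.011 in set 1 and with set as a term, and glutamate receptor genes at 0.026 in the later sets. Without single profiles, Tmem119 ran from -0.062 to 0.018, Gabra6 from -0.76 to 0.055 and Cbln3 from -0.58 to 0.077, both of these highest without ILS replicate 4, and means of neuron genes ran from -0.013 to 0.015, GABA-A receptor genes from -0.037 to 0.023, glutamate receptor genes from -0.025 to 0.011, and opioid and related genes from -0.0058 to 0.044. Depth is unknown for the miRNA values, and the floor of the variance-stabilized table limits low miRNAs.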

Other observations

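The test of the even split and the correlation below were chosen after the values were seen; the test of batch was written down beforehand.

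Across strains, miR-200a-3p rose and fell with miR-182-5p. They had Pearson r = 0.926 and Spearman rho = 0.914 over 59 strains (permutation p = 1e-05 for each, the smallest that 100000 resamples can give), the only pair tested. Without the 2 strains farthest from the median of miR-200a-3p, r was 0.928. After removal of batch shares r was 0.940, and among the 8 strains sequenced only in batch 5 it was 0.977. The 8 measured members of the miR-200 family had a mean pairwise r of 0.952 after removal of batch shares. Members of the list of pituitary, pineal and sensory miRNAs, which also holds miR-7 and miR-375, had a mean of 0.172.

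The 3 features at the top of a ranking had strain values in separate ranges. They were picked for this, and how wide a gap chance gives over all features was not tested. On the variance-stabilized scale, an unannotated feature was at or below 5.03 in 25 strains and at or above 6.29 in 34 strains. These ranges hold 94.5% of its variance, a share that is no support in itself because the feature was picked for its gap. miR-5121 was at or below 5.79 in 33 strains and at or above 6.13 in 26. Another unannotated feature was at or below 5.87 in 25 and at or above 6.23 in 34. If sequencing batch had set these ranges, it would hold most of the variance, but batch shares held at most 18.97% in these 3 features. A hypothesis is that each follows a variant of a single locus that segregates in the panel, which may split strains evenly: the smallest range held 25 of 59 strains, and an even split allows as few as 22. Any gap near the middle of the ordered strains would meet this bound, so meeting it is no support for a locus. Genotypes of the strains were not used here, so whether such a variant changes the amount of RNA or only its detection is open, and mean abundance was low, at 10.3 normalized units for the feature with the widest gap.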
